A study of Mus musculus with 12 samples.

How the data were processed

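The study sequenced RNA from the piriform cortex of 12 mice on a C57BL/6 background, all aged 12 months. Per the labels, 6 animals were heterozygous for the Q140 knock-in allele of Htt, which carries an expanded CAG repeat in its opening exon, and 6 were wild type, with 3 males and 3 females of each genotype. Per the labels' protocols, RNA was taken with a Qiagen RNeasy kit and libraries were made with the Illumina TruSeq stranded preparation. All libraries came from plate 1. Each library is a separate animal, so the p-values measure the spread between animals.

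The deposited count table holds whole numbers of reads per gene and animal, not normalized. The submitters' processing notes name STAR 2.7.5c, SAMtools 1.10 and HTSeq 0.12.3 with the builds GRCm38 and mm10. The strand setting of the counting and the annotation release are not given in the sources used here, so reads of a gene and of an overlapping or antisense gene cannot be told apart. The deposited FPKM table was made by the authors from the same counts: over 14961 genes with at least 20 counts, the length implied by count, FPKM and column total had a coefficient of variation of at most 5.6e-09 across the animals. FPKM carries no correction for library composition beyond the column total. Each table has 48795 genes with symbols and identifiers. Coordinates, lengths and GC contents came from GENCODE M21 on GRCm38, which matched 48435 of the identifiers.

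Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, after TMM normalization and the default expression filter of edgeR by genotype, which kept 17725 genes. The genotype comparison used sex as a covariate. The comparisons within females and within males, and the difference of the Q140 effect between the sexes, were contrasts in a model of the 4 groups of genotype and sex over all 12 animals. Males were compared with females with genotype as a covariate. Adjusted p-values are Benjamini-Hochberg values over the genes tested, two-sided, and 0.05 was the threshold. CPM values use the TMM-scaled library sizes. Other comparisons between groups of animals are exact permutation tests, two-sided. Where the wild types of a comparison had 1 to 3 reads of a named gene in all, a ratio of reads scaled by library size is given with a binomial counting interval, and against 0 reads a lower bound with a floor of 3 counts over the group; this was chosen after the values were seen.

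Gene lists, 40 in all, were fixed from textbook markers, pathways and complexes before the data were examined, as were the groups, the tests and most alternatives. The 39 lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. The lists hold 853 tested genes, 29 of them in more than 1 list, so the lists are not independent. Symbols absent from the tables numbered 3. Genes were named by a rule: Htt, the 12 genes with the largest fold each way among those that passed, had a mean of at least 1 CPM and had all 6 Q140 animals on that side of the wild type mean, up to 4 members of each list by smallest p, up to 5 genes each way in each sex, the 3 with the smallest p where none passed, the sex check genes with up to 5 autosomal genes, and up to 5 genes within 10 Mb of Htt. The restriction of list members to those with an unadjusted p below 0.05, or else the 1 with the smallest p, was set afterwards. Not every gene that the rule names is given in the text.

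Alternatives were other size factors, other filters, DESeq2 1.42.0, limma voom with sample quality weights, limma on log2 FPKM with pseudocounts of 0.1 and 1, each animal left out, a surrogate variable from sva 3.50.0, marker list means as covariates, and fits within the name prefixes and numbers of the animals. The animal names carry a prefix whose meaning the labels do not state. RFckQ covers 4 wild types and 1 Q140 animal, RFQ 1 wild type and 3 Q140 animals and FMQ 1 wild type, and 2 Q140 animals, numbers 1 and 2, have none. Offsets that remove each library's trend with gene length and GC content, a covariate of the meningeal list, and fits without wild types 3 and 6 were added after the data were examined.

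The fits were tested on simulated counts drawn from the animals' means and library sizes, with 200 genes changed. Of genes changed by 1.25, 1.5 and 2 times, the genotype comparison recovered 29.9%, 73.1% and 83.3%, with 10 of 134 calls false over 17587 genes. For females the shares were 11.9%, 59.7% and 66.7%, for males 11.9%, 53.7% and 66.7%, for the difference between the sexes 5.97%, 28.4% and 54.5%, and for males against females 26.9%, 73.1% and 72.7%. Camera found a list of 25 changed genes and called no other list. The simulated genes varied independently of one another, so this does not test the preset correlation between genes. The offsets reduced 3815 calls from a simulated length trend to 0. Pairs of animals within a genotype, 30 in all, differed by 6.36 to 27.5 times the counting noise (chi-square over its degrees of freedom, genes with at least 20 counts in the pair), so none is a library counted again. Plots were drawn with matplotlib 3.10.9.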

Results

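RNA-seq read counts were obtained from the piriform cortex, the main cortical target of the olfactory bulb, of 6 heterozygous Q140 knock-in mice and 6 wild types, to compare transcription in this model of Huntington's disease with that of normal animals. Total counts ranged from 19587208 to 35198602 per animal, with means of 30.6 ± 6.41 M in Q140 and 28.9 ± 3.15 M in wild types (SD, n = 6 each, exact permutation p = 0.569). Between 23215 and 24634 genes had at least 1 read. A count of 0 allows a level of up to 0.153 CPM in the shallowest library and 0.0852 CPM in the deepest (3 counts, counting error only). Mitochondrial transcripts took 7.02 ± 0.770% of counts in Q140 and 6.36 ± 0.557% in wild types (exact permutation p = 0.113). TMM factors, which reflect library composition, were 1.02 ± 0.0177 in Q140 and 0.984 ± 0.0110 in wild types without overlap (exact permutation p = 0.00216, the smallest that 6 against 6 can give).

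Htt itself (ENSMUSG00000029104, chromosome 5, 34761740 to 34912534, GRCm38), the gene that carries the knock-in, fell by 22.6% in Q140 cortex. Its level was 196 ± 8.15 CPM in wild types and 151 ± 8.19 CPM in Q140 (SD, n = 6 each), a log2 fold change of -0.37 (SE 0.0428, edgeR adjusted p = 0.000203). The 6 Q140 animals lay between 143 and 164 CPM, and the wild types between 180 and 204 CPM. The count covers the whole gene and sums both alleles. Wild type 4, at 180 CPM, stood below the other wild types, which began at 197 CPM.

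Some genes for transcription factors of embryonic patterning rose in Q140 cortex. One list held developmental transcription factors that polycomb keeps silent in adult neurons. Of its 22 tested members 11 rose, 0 fell and 11 did not pass, with 11 higher and 1 lower adjusted over the list alone. Listed genes with too few reads were left out by the expression filter. A gene near 0 in wild types, such as Wt1, entered the test only through its level in Q140. Wt1, a zinc finger factor of kidney and gonad development, went from 0.0362 ± 0.0380 to 1.76 ± 0.543 CPM (SD, n = 6 each), a log2 fold change of 5.51 (SE 0.373, adjusted p = 4.66e-06). Lmx1b, a factor of midbrain and limb development, rose from 0.251 ± 0.146 to 3.18 ± 1.63 CPM, log2 fold change 3.65 (SE 0.432, adjusted p = 0.000226). Onecut2 rose from 4.46 ± 1.95 to 22.3 ± 6.34 CPM, log2 fold change 2.33 (SE 0.310, adjusted p = 0.000527), and its paralog Onecut1 rose as well (adjusted p = 4.89e-05), to 0.664 CPM. The list shifted upward by camera (adjusted p = 3.11e-08, but adjusted p = 0.157 with an estimated correlation). Twist1, a mesodermal factor, rose by 2.54 on the log2 scale (SE 0.385, adjusted p = 0.0012), and the homeobox gene Nkx2-9 by 1.57 (SE 0.196).

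Hoxc4 and Hoxc6, of the Hox clusters, which pattern the body axis, also rose. They were the only 2 of 39 listed Hox genes to pass the expression filter. Wild types held almost no reads of them, so they passed it through the Q140 animals alone, and their rises do not speak for the list. Hoxc6 went from 0.0496 ± 0.0619 to 0.722 ± 0.193 CPM (SD, n = 6 each, adjusted p = 0.000459). Hoxc4 had 1 read in all wild types together and 106 in Q140, a ratio of 97.1 with a 95% counting interval from 17.1 to 3872. Both passed too when adjusted over the list alone, and with fewer than 3 members the list had no camera test. C130021I20Rik, which lies beside Lmx1b on chromosome 2 (33641193 to 33646354, against 33560965 to 33640511 for Lmx1b), rose from 0.0451 ± 0.0841 to 2.78 ± 1.04 CPM, with 4 wild types at 0. The list mean of the developmental factors separated the genotypes completely (exact permutation p = 0.00216), and wild type 4 was the highest wild type, at 0.03 against -0.36 or lower for the others on a centred log2 scale. The mean of the meningeal marker list, tissue that lies on the cortex surface, was -2.30 in wild type 3 and 1.21 in wild type 4 on that scale.

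Among the other genes with large rises were Tmc3, a relative of the hair cell transduction channels, at 2.85 on the log2 scale (SE 0.218, adjusted p = 1.38e-05), the tight junction gene Cldn14 at 1.66 (SE 0.227), and Nmbr, the neuromedin B receptor, at 1.55 (SE 0.297). Siglec1, a macrophage lectin, rose by 1.43 (SE 0.266), Il12rb1, a cytokine receptor, by 1.37 (SE 0.250), the G protein regulator Rgs13 by 1.36 (SE 0.211) and Gm6089 by 1.66 (SE 0.344), or by 2.31 without wild type 6, in which Gm6089 stood at the Q140 level (2.54 CPM). Large falls were those of Cpne9, a calcium-binding copine, from 36.6 ± 4.05 to 12.6 ± 3.21 CPM (SD, n = 6 each, log2 fold change -1.54, SE 0.130, adjusted p = 2.52e-05), Susd2 from 41.4 ± 7.59 to 15.7 ± 3.16 CPM (-1.40, SE 0.141). Plk5, a polo-like kinase of neurons, went from 88.7 ± 17.2 to 35.6 ± 4.66 CPM (-1.32, SE 0.125). Dgat2l6 (-1.92, SE 0.186) and the cone arrestin gene Arr3 (-1.61, SE 0.299) fell as neighbours on chromosome X, at 100524838 to 100546144 and 100605497 to 100618493. Trim54 (-1.69), Gm9754 (-1.65), Gm12031 (-1.52), Arhgef39 (-1.42), Alox12b (-1.41), Tnfrsf8 (-1.31) and Npsr1 (-1.29) completed the 12 falls named by size. Tnfrsf8 passed in 15 of 29 alternatives (-1.80 to -0.46) and Npsr1 in 11 (-1.54 to -0.39). Tmc3, Nmbr, Trim54, Gm9754 and Npsr1 overlap genes on the opposite strand and Onecut1 overlaps Gm20649 on its own strand, so their values are uncertain.

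**Figure D1:**
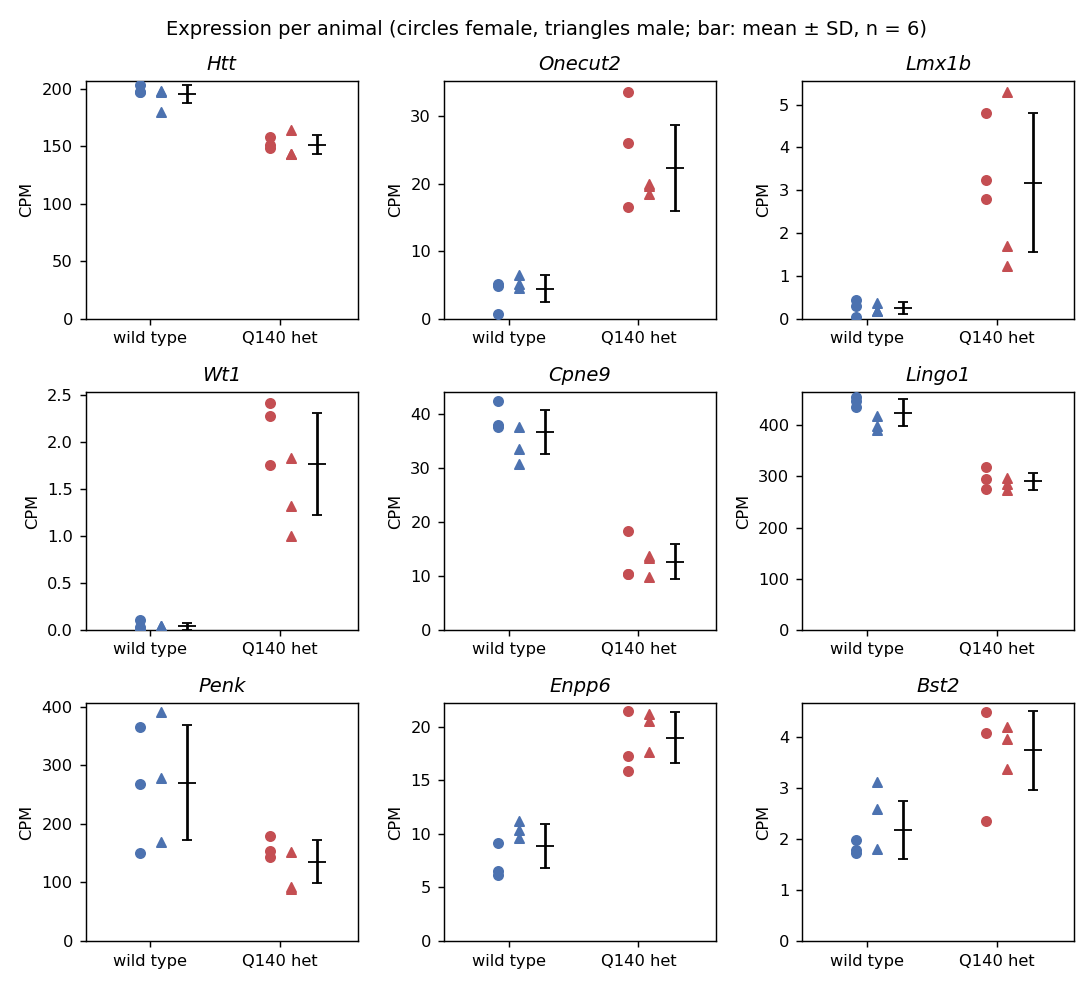
Expression in CPM (linear axes from 0) of 9 genes in each wild type (blue) and Q140 animal (red). Circles are females, triangles males, and the black bar gives the mean ± SD of 6 animals; Htt lies between 143 and 164 CPM in Q140 animals and between 180 and 204 CPM in wild types.

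Many genes of excitatory neurons and synapses fell. Of 14 excitatory neuron markers 7 fell, 0 rose and 7 did not pass, with 9 lower adjusted over the list alone. Examples are Lingo1, an inhibitor of neurite growth, from 425 ± 26.6 to 291 ± 16.6 CPM (SD, n = 6 each, log2 fold change -0.54, SE 0.0436, adjusted p = 1.71e-05), Arpp21 (-0.50, SE 0.0538) and Slc30a3, the zinc transporter of synaptic vesicles (-0.57, SE 0.0796). The camera adjusted p of this list was 6.24e-08, and adjusted p = 0.157 with an estimated correlation. Among 30 genes of synaptic vesicles and release 13 fell, 0 rose and 17 did not pass (18 lower adjusted over the list alone), including the active zone scaffold Bsn (-0.47, SE 0.0615), Sv2b (-0.47, SE 0.0733) and the fusion protein gene Snap25, from 3077 ± 171 to 2416 ± 207 CPM (-0.35, SE 0.0595). That list had a camera adjusted p of 1.24e-08, and adjusted p = 0.203 with an estimated correlation.

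Of 36 glutamate receptor and postsynaptic scaffold genes, with Dlg2 counted under 2 identifiers, 15 fell, 1 rose and 20 did not pass, against 23 lower and 1 higher adjusted over the list alone. Dlgap1 (-0.34, SE 0.0578) and the NMDA receptor subunit Grin2a (-0.28, SE 0.0535) were among them (camera adjusted p = 1.22e-08, but adjusted p = 0.157 with an estimated correlation). Voltage-gated potassium channels gave 13 falls, 0 rises and 24 that did not pass among 37, with 20 lower adjusted over the list alone, led by Kcnh4 (-0.85, SE 0.0887) and Kcnh3 (-0.32, SE 0.0444). Their camera adjusted p was 2.28e-09, and adjusted p = 0.157 with an estimated correlation. Among 17 GABA receptor genes 2 fell, Gabrd of extrasynaptic receptors (-0.69, SE 0.0531, adjusted p = 1.38e-05) and Gabbr2 (-0.37, SE 0.0752), 0 rose and 15 did not pass, with 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00759, and adjusted p = 0.261 with an estimated correlation).

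Inhibitory neuron markers fell in 4 of 22, with 0 higher and 18 that did not pass, and 5 lower adjusted over the list alone: Lamp5 (-0.62, SE 0.0867), somatostatin, Sst (-0.76, SE 0.165), Adarb2 (-0.28, SE 0.0722) and Lhx6 (-0.43, SE 0.131), which passed in 10 of 29 alternatives. Camera gave an adjusted p of 0.0468, and adjusted p = 0.271 with an estimated correlation. Of 19 neuropeptide genes 3 fell, 0 rose and 16 did not pass, with 9 lower adjusted over the list alone. The opioid precursors Penk, from 270 ± 98.5 to 135 ± 36.7 CPM (SD, n = 6 each, log2 fold change -1.02, SE 0.236, adjusted p = 0.0141), and Pdyn (-1.02, SE 0.267) fell along with Sst (camera adjusted p = 0.00759, and adjusted p = 0.157 with an estimated correlation). Penk and Pdyn were also the only 2 of 24 striatal projection neuron markers to pass, both lower, and likewise adjusted over the list alone. Penk overlaps A830012C17Rik on the opposite strand, so its value is uncertain. The striatal list, a measure of neighbouring striatum in the dissection, had a camera adjusted p of 0.538, and its mean in wild type 6 was -1.59 against -0.45 or higher in the other wild types.

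Some activity-regulated and clock genes fell. Of 24 immediate early genes 10 fell, 0 rose and 14 did not pass, against 14 lower and 1 higher adjusted over the list alone. Egr2 went from 19.7 ± 3.93 to 8.57 ± 3.35 CPM (SD, n = 6 each, log2 fold change -1.19, SE 0.191, adjusted p = 0.00177), and the phosphatase gene Dusp1 fell by 0.49 (SE 0.0808). Camera gave an adjusted p of 6.81e-06, and adjusted p = 0.261 with an estimated correlation. Of 17 circadian clock genes 9 fell, 0 rose and 8 did not pass, with 11 lower adjusted over the list alone, among them the output regulators Tef (-0.25, SE 0.0359) and Hlf (-0.32, SE 0.0524), Bhlhe40 (-0.58, SE 0.0894) and Per1 (-0.48, SE 0.0902). The clock list had a camera adjusted p of 1.01e-05, and adjusted p = 0.157 with an estimated correlation. Cholesterol synthesis genes fell in 13 of 26, with 0 higher and 13 that did not pass, and 17 lower adjusted over the list alone. Hmgcs1, of the mevalonate pathway (-0.29, SE 0.0390), and Lss, of sterol ring closure (-0.26, SE 0.0438), were among these (camera adjusted p = 3.41e-07, and adjusted p = 0.251 with an estimated correlation).

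Many myelin and interferon-stimulated genes rose. Of 24 oligodendrocyte and myelin genes 11 rose, 1 fell and 12 did not pass, against 15 higher and 1 lower adjusted over the list alone. Enpp6, a marker of newly forming oligodendrocytes, went from 8.82 ± 2.05 to 19.0 ± 2.35 CPM (SD, n = 6 each, log2 fold change 1.12, SE 0.115, adjusted p = 8.9e-05), with Mog (0.61, SE 0.0991) and Bcas1 (0.50, SE 0.0830) also higher. The list's mean was -0.16 ± 0.202 in wild types and 0.16 ± 0.169 in Q140 on a centred log2 scale (exact permutation p = 0.0152), a difference that accompanies the falls above (camera adjusted p = 5.93e-06, but adjusted p = 0.5 with an estimated correlation). Among 11 precursor markers 0 rose, 0 fell and 0 passed adjusted over the list alone, and their median of -0.0023 and mean of 0.03 differed in sign (camera adjusted p = 0.907). Interferon-stimulated genes rose in 15 of 25, with 0 lower and 10 that did not pass, and 20 higher adjusted over the list alone. Examples are Bst2, from 2.18 ± 0.566 to 3.75 ± 0.775 CPM (log2 fold change 0.80, SE 0.173), Xaf1 (0.50, SE 0.107) and the class I molecule H2-D1 (0.47, SE 0.0891), and camera gave an adjusted p of 3.85e-10, but adjusted p = 0.177 with an estimated correlation.

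Among astrocyte, microglia and vessel markers fewer genes passed. Of 16 astrocyte markers 1 rose, S100b (0.56, SE 0.0704, adjusted p = 0.000351). There 2 fell, the bicarbonate transporter Slc4a4 (-0.30, SE 0.0655) and the glutamate transporter Slc1a2 (-0.31, SE 0.0823), and 13 did not pass, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.858). Reactive astrocyte genes rose in 5 of 22, with 0 lower and 7 higher adjusted over the list alone, including Vim (0.56, SE 0.138) and Serpina3n (0.43, SE 0.124). Their camera adjusted p was 6.77e-05, but adjusted p = 0.454 with an estimated correlation. Homeostatic microglia markers rose in 2 of 18, Sall1 (0.22, SE 0.0543) and Tmem119 (0.27, SE 0.0797), with 6 higher adjusted over the list alone (camera adjusted p = 0.00404, but adjusted p = 0.561 with an estimated correlation). Disease-associated microglia genes rose in 6 of 21, with 0 lower, and gave 10 higher and 1 lower adjusted over the list alone. Csf1 (0.35, SE 0.0754) and Ctsz (0.35, SE 0.0860) were among them (camera adjusted p = 0.000177, but adjusted p = 0.454 with an estimated correlation). Of 22 endothelial and pericyte markers 1 rose, Ly6c1 (0.33, SE 0.0857), also the only 1 adjusted over the list alone (camera adjusted p = 0.00404, but adjusted p = 0.561 with an estimated correlation).

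Several tissue lists shifted by camera without a member that passed, over all genes or adjusted over the list alone. All 15 meningeal markers were positive in sign (median 0.49, camera adjusted p = 0.00727, but adjusted p = 0.591 with an estimated correlation), with Pcolce at 0.61 (SE 0.340). On a centred log2 scale the meningeal mean was -2.30 in wild type 3 and -0.59 to 1.21 in the other wild types. In Q140 it was -0.27 to 1.12 (exact permutation p = 0.262). For 13 complement genes the median was 0.22 (camera adjusted p = 0.0167, but adjusted p = 0.561 with an estimated correlation). The complement mean was -0.70 in wild type 3, -0.24 to 0.49 in the other wild types and -0.10 to 0.46 in Q140 (exact permutation p = 0.18). The 13 mitochondrially encoded genes had a median of 0.15 (camera adjusted p = 0.0457, but adjusted p = 0.565 with an estimated correlation), and mt-Nd3, at 0.27 (SE 0.124), is uncertain since nuclear copies share its reads. The mean of that list on a centred log2 scale was 0.19 to 0.23 in Q140 animals 1 to 4. In Q140 animals 5 and 6 it was -0.2459 and -0.2255, below every wild type (exact permutation p = 0.24). Choroid plexus and ependymal markers (7 genes, median 0.13, camera adjusted p = 0.464) and red blood cell genes (5 genes, median 0.16, camera adjusted p = 0.236) had 0 calls either way and did not shift.

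Some genes of protein synthesis and housekeeping rose by small amounts. Of 76 cytosolic ribosomal protein genes 16 rose, 0 fell and 60 did not pass, with 27 higher adjusted over the list alone, as for Rps9 (0.21, SE 0.0437) and Rpl4 (0.15, SE 0.0349). The camera adjusted p was 3.85e-10, but adjusted p = 0.261 with an estimated correlation. Ribosomal protein genes have many processed pseudogenes that can share their reads. Nuclear oxidative phosphorylation genes rose in 7 of 77, with 0 lower and 6 higher adjusted over the list alone, such as Uqcrh (0.20, SE 0.0428) and Sdha (0.13, SE 0.0325), at a camera adjusted p of 2.16e-07, but adjusted p = 0.454 with an estimated correlation. Autophagy and lysosome genes rose in 4 of 27, with 0 lower and 6 higher adjusted over the list alone, among them progranulin, Grn (0.19, SE 0.0424), Npc2 (0.22, SE 0.0585) and Lamp1 (0.14, SE 0.0419), the last past in 11 of 29 alternatives, with a camera adjusted p of 0.000218, but adjusted p = 0.203 with an estimated correlation. Endoplasmic reticulum stress genes rose in 3 of 22, Pdia3 (0.22, SE 0.0558), Herpud1 (0.21, SE 0.0548) and Xbp1 (0.29, SE 0.0794), with 7 higher adjusted over the list alone (camera adjusted p = 0.00204, but adjusted p = 0.5 with an estimated correlation). That list's mean was 0.26 and 0.32 in Q140 animals 1 and 2 and between -0.13 and 0.01 in the other 10 animals (exact permutation p = 0.294). Of 14 glucocorticoid-responsive genes 1 rose, the lipid droplet gene Plin4 (0.99, SE 0.293), which passed in 13 of 29 alternatives, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0197, but adjusted p = 0.561 with an estimated correlation). The mean of this list was 0.49 and 0.48 in Q140 animals 1 and 2 and 0.10 or lower in the other 10 animals (exact permutation p = 0.152). Heat shock genes went both ways, with 3 of 18 higher, among them Hspa8 (0.26, SE 0.0478) and Cryab (0.39, SE 0.0787), and 2 lower, among them Hspa1b (-0.57, SE 0.156), against 4 and 4 adjusted over the list alone (camera adjusted p = 0.114).

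**Figure D2:**
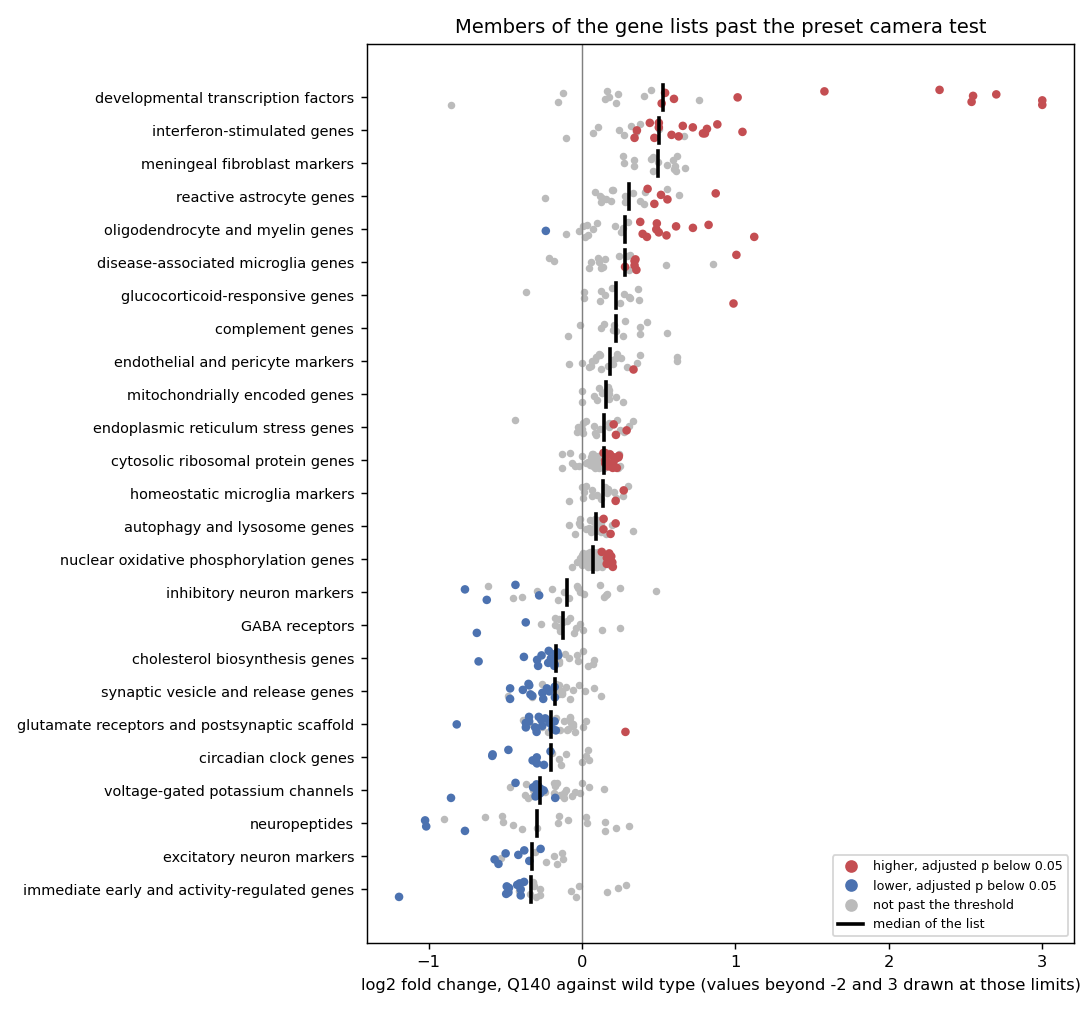
Log2 fold changes (Q140 against wild type, horizontal axis) of the members of the 25 lists that passed camera with the preset correlation. Red and blue points passed the threshold of 0.05, grey points did not, and the black bar is the list's median; the developmental transcription factors have a median of 0.53 and the excitatory neuron markers one of -0.32.

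Across the genome 1982 of 17725 tested genes passed, 797 higher and 1185 lower in Q140. Of these, 365 changed by at least 1.5 times. By camera with the preset correlation 25 of 39 lists passed, 15 upward and 10 downward, and their medians kept their sign under each other scaling tried. With an estimated correlation 0 passed, 9 had an unadjusted p below 0.05 and fry called 14 by direction. On FPKM values, which lack the TMM factors, limma called 2256 genes with 1555 higher and 701 lower, a share of 68.9% higher against 40.2% here. Fewer genes passed without Q140 animal 2 (1139) or 3 (1314), without wild type 1 (1197) or 3 (1231), without wild types 3 and 6, whose dissection markers lay apart (862), and with the mean of the meningeal (1062) or oligodendrocyte list (195) as a covariate. Within the prefixes RFckQ and RFQ, 9 animals with prefix and sex as covariates, 81 genes passed, all with the sign they have here. Among the 5 animals of the numbers 150 and 161, with the number as a covariate, 1 passed, Onecut2.

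Medians of several of the 25 lists moved by over 1.5 times in fits with list means as covariates, within the prefixes or on FPKM. With the oligodendrocyte list mean as a covariate, interferon-stimulated genes went from 0.50 to 0.27, developmental transcription factors from 0.53 to 0.31, excitatory neuron markers from -0.32 to -0.20, glutamate receptors from -0.20 to -0.13 and GABA receptors from -0.13 to -0.06. In that fit reactive astrocyte genes went from 0.31 to 0.16, disease-associated microglia genes from 0.28 to 0.10, endothelial markers from 0.18 to 0.03, complement genes from 0.22 to 0.12, meningeal markers from 0.49 to 0.18 and glucocorticoid-responsive genes from 0.22 to 0.09. Endoplasmic reticulum stress genes went there from 0.15 to 0.07, autophagy and lysosome genes from 0.09 to 0.05, oxidative phosphorylation genes from 0.07 to 0.03 and mitochondrially encoded genes from 0.15 to -0.01. With the meningeal list mean, medians were 0.12 for reactive astrocytes, 0.11 for disease-associated and 0.08 for homeostatic microglia (from 0.13), 0.06 for endothelium, 0.06 for complement, 0.09 for mitochondrially encoded and 0.14 for glucocorticoid-responsive genes. Within the prefixes RFckQ and RFQ, immediate early genes went from -0.33 to -0.11, neuropeptides from -0.29 to -0.12, inhibitory neuron markers from -0.10 to -0.03, synaptic vesicle genes from -0.18 to -0.11 and GABA receptors to -0.06. There reactive astrocytes were at 0.18, disease-associated and homeostatic microglia at 0.17 and 0.08, endothelium at 0.05, meninges at 0.32, endoplasmic reticulum stress at 0.07, mitochondrially encoded genes at 0.05 and glucocorticoid-responsive genes at 0.10. On FPKM with a pseudocount of 1, neuropeptides were at -0.17, potassium channels at -0.16 (from -0.27), excitatory neuron markers at -0.22, cholesterol synthesis at -0.11 (from -0.17), disease-associated microglia at 0.16, interferon-stimulated genes at 0.31 and oxidative phosphorylation at 0.12. With a pseudocount of 0.1 autophagy and lysosome genes were at 0.14 and, without a filter, inhibitory neuron markers at -0.03 and GABA receptors at -0.08.

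The region around Htt was examined because a knock-in allele is inherited together with the DNA around it. Within 10 Mb on either side (chromosome 5, 24761740 to 44912534) 34 of 196 tested genes changed, 12 higher and 22 lower, or 17.3%, against 11.1% of the 17476 genes elsewhere (odds ratio 1.68, 95% interval 1.12 to 2.45, Fisher's exact p = 0.00847, two-sided). Gm2420 rose from 0.0323 ± 0.0398 to 0.708 ± 0.240 CPM (SD, n = 6 each, adjusted p = 0.000207), and Abhd1, an abhydrolase gene, rose by 1.15 on the log2 scale (SE 0.123, adjusted p = 0.000115). Trim54, of muscle microtubules, fell from 8.36 ± 0.713 to 2.63 ± 1.02 CPM, and Slc30a3 fell by 0.57. Abhd1 overlaps Preb on the opposite strand. Within 20 Mb the ratio was 1.35 (Fisher's exact p = 0.0776).

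**Figure D3:**
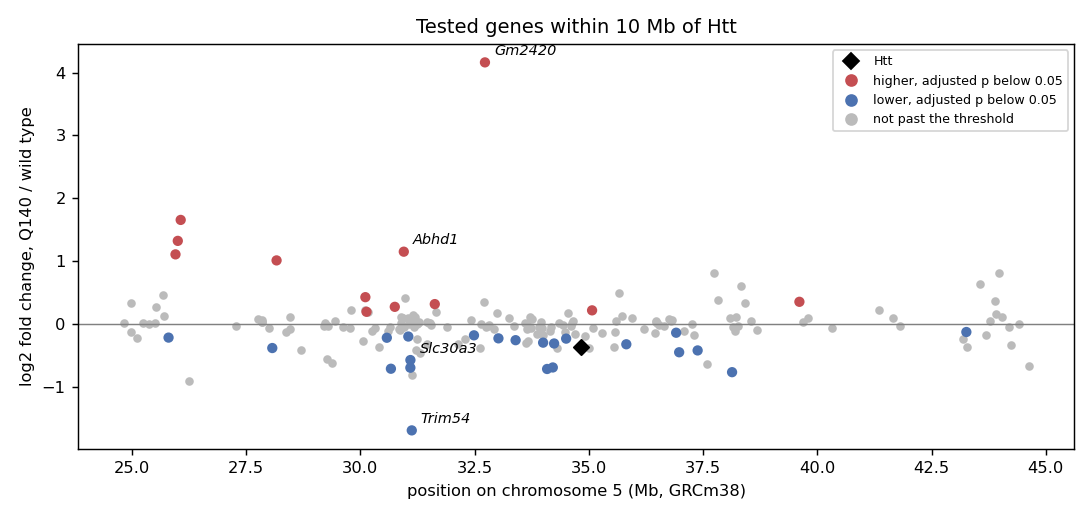
Log2 fold change (Q140 against wild type) of the 196 tested genes within 10 Mb of Htt, against position on chromosome 5 in Mb. Red genes were higher and blue lower at an adjusted p below 0.05, grey genes did not pass, and the black diamond is Htt at -0.37.

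In females, Q140 cortex had higher Tmc3 (log2 fold change 3.49, SE 0.254, adjusted p = 6.61e-05), Wt1 (5.48, SE 0.503), Onecut1 (2.89, SE 0.315) and Abhd1 (1.40, SE 0.151) than wild type cortex. C130021I20Rik rose too (adjusted p = 0.000897), with 334 reads in 3 Q140 females against 2 in 3 wild type females, a ratio of 146 (95% counting interval 40.1 to 1209). Lingo1 fell by 0.59 (SE 0.0598, adjusted p = 0.000638), Tmem145 by 0.75 (SE 0.0710), the lymphocyte and neuron transcription factor gene Pou2f2 by 0.69 (SE 0.0717), the semaphorin receptor Plxnd1 by 0.55 (SE 0.0579) and the chemokine receptor Ackr1 by 0.72 (SE 0.0613). Ackr1 shares exon sequence with Cadm3 on its strand, so its value is uncertain. By edgeR, 1249 genes passed with 3 animals per genotype, 502 higher and 747 lower, against 582 and 418 on FPKM. The count fell to 228 without Q140 animal 2, 622 without Q140 animal 1, 433 without wild type 3 and 678 without wild type 6.

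In males, Tmc3 (log2 fold change 2.35, SE 0.229, adjusted p = 0.00114) and C130021I20Rik (5.13, SE 0.721) were higher in Q140. Wt1 rose with 115 reads in 3 Q140 males against 2 in 3 wild types, a ratio of 55.8 (95% counting interval 15.1 to 467), and Gm2420, at 0 in all 3 wild types, was at least 16.5-fold higher, against a floor of 3 counts over the group. Ackr1 fell by 0.67 (SE 0.0622, adjusted p = 0.00114), Gabrd by 0.68 (SE 0.0775), Lingo1 by 0.49 (SE 0.0599), the pyruvate dehydrogenase phosphatase gene Pdp1 by 0.53 (SE 0.0610) and Gm9754 by 2.21 (SE 0.266). By edgeR, 248 genes passed, 78 higher and 170 lower, against 348 and 124 on FPKM. The calls of the sexes shared 45 genes higher and 104 lower, where independent lists would share 2.21 and 7.16. Both comparisons used the same estimate of each gene's spread, so their calls could overlap beyond these numbers even without shared effects. The count in males was 41 without wild type 1, 58 without wild type 5, 84 without Q140 animal 3, 55 without Q140 animal 6 and 747 without Q140 animal 5.

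The Q140 effect on Tmem145 was -0.75 in females and -0.09 in males, a difference of 0.65 (SE 0.101, adjusted p = 0.344), the smallest p among the tests of a difference between the sexes. Lmtk3, a neuronal kinase gene, had -0.38 in females and 0.11 in males (adjusted p = 0.471), and Cep131, of centriolar satellites, -0.45 and 0.16 (adjusted p = 0.471). By edgeR 0 genes passed and 1633 had an unadjusted p below 0.05, whereas DESeq2 called 25 genes and voom 1, which was Tmem145. Of the gene lists 15 passed camera with the preset correlation and 0 with an estimated one, where 0 also had an unadjusted p below 0.05 and fry called 0 by direction. The glucocorticoid-responsive list had medians of 0.34 in females and 0.02 in males (camera adjusted p = 1.04e-05, but adjusted p = 0.749 with an estimated correlation), and 5 members were lower in the test of the difference adjusted over the list alone. Its mean on a centred log2 scale was 0.49 in Q140 animal 1 and 0.48 in Q140 animal 2, and between -0.28 and 0.10 in the other 10 animals.

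Sex was recovered from the chromosomes in every animal. Xist, which silences one X chromosome in females, stood at 865 CPM or more in the 6 females and at 0.224 CPM or less in the 6 males. The Y-linked gene Ddx3y was at 61.8 CPM or more in males and at 0.0306 CPM or less in females, and Uty, Kdm5d and Eif2s3y were higher in males as well. In all, 4 of the 5 tested genes of this check were higher in males and 1 lower, over all genes and adjusted over the list alone (camera adjusted p = 1.92e-17, and adjusted p = 0.000304 with an estimated correlation). Among autosomal genes the MAP kinase phosphatase gene Dusp4 was at 22.2 CPM in females and 11.9 CPM in males (log2 fold change -0.90, SE 0.0791, adjusted p = 3.58e-05), Irs2, of insulin signalling, at 97.5 and 60.9 CPM (-0.68, SE 0.0611). The clock gene Per2 stood at 76.0 and 47.9 CPM (-0.67, SE 0.0740). Fosb differed by -0.52 (SE 0.0660) and Tob1 by 0.35 (SE 0.0450). Of 24 immediate early genes 8 were lower and 1 higher in males, against 12 and 3 adjusted over the list alone (camera adjusted p = 0.000397, but adjusted p = 0.456 with an estimated correlation). By edgeR 116 genes passed, 35 higher and 81 lower in males, with 45 to 146 on leaving out each animal, 350 by DESeq2 and 20 higher and 27 lower on FPKM. Genotype changed none of the 5 sex check genes, over all genes or adjusted over the list alone (camera adjusted p = 0.806).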

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

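The tests of a smaller share of neurons and of more white matter, and the settings with length and GC offsets, with the meningeal list and without wild types 3 and 6, were chosen only after the result was seen.

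The 11 developmental factor genes that rose, a median log2 fold change of 2.33, were weighed against tissue from outside the piriform cortex and against breeding. With the meningeal list mean as a covariate their median was 2.17 and all 11 still passed. In the 9 animals of the prefixes RFckQ and RFQ it was 1.75 with 3 of 11 past the threshold. Fewer animals, and the overlap of prefix with genotype, widen the errors there. Both values stay above the bound of 50% set for these tests. The meningeal value argues against meningeal tissue as the whole cause. The prefix fit cannot decide, since RFckQ holds 1 Q140 animal, number 4, and RFQ 1 wild type, number 4. The 11 genes were also chosen as calls among the same animals. Hindbrain or spinal tissue cannot be told apart from the alternatives, since 10 hindbrain genes had a median of 0.22 and the 2 that passed went opposite ways, Glra1 at -1.35 (adjusted p = 0.0348) and Ddc at 0.51 (adjusted p = 0.0071). An effect of the Q140 genotype stays open, untested.

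The fall of neuronal genes covers 49 calls among 117 members of the excitatory, synaptic vesicle, glutamate and potassium channel lists, 48 of them lower and 1 higher. Oligodendrocyte members had a median of 0.30 against 0.02 for astrocyte and precursor members, without shared members (permutation of genes, p = 5e-04). That test exchanges genes, not animals, so its p does not measure the spread between animals. Over animals, exact permutation p-values of the list means were 0.0152 for oligodendrocytes, 0.6 for astrocytes and 0.604 for precursors. A smaller share of neurons would raise all other cell types alike. The medians of these lists were not alike, but their difference was not tested over animals. Homeostatic and disease-associated microglia (0.13 and 0.28) and endothelium (0.18), whose medians were higher in Q140, were not in this test. The test therefore cannot decide whether a smaller share of neurons was none, part or the whole of the cause. Length and GC offsets kept 87.8% of the calls, which argues against library bias as the whole cause. The striatal covariate kept 100%, but a covariate unrelated to genotype can remove little of a genotype difference. The striatal list mean was 0.02 ± 0.937 in wild types and -0.02 ± 0.414 in Q140 (SD, n = 6 each, exact permutation p = 0.924). It thus gave no sign of a different share of striatal tissue, though its spread was wide. With the oligodendrocyte list mean as a covariate the median of the calls went from -0.30 to -0.22. Of the 49 calls 6 still passed, as their median SE rose from 0.0615 to 0.0794. The list mean is an imperfect measure of white matter and correlated with genotype at 0.675. That fit therefore cannot decide whether more white matter in the Q140 dissections was none, part or the whole of the cause. An effect of the genotype on neurons or oligodendrocytes stays open, untested.

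Around Htt, 3.58% of 2629 windows of 20 Mb across the genome had at least as large a share of called genes (17.4% at Htt, median 10.6%, maximum 26.1%). Flanking DNA of the strain in which the allele was made is therefore a candidate explanation for the changes of Gm2420, Abhd1 and Trim54. It is one too for other called genes of the window, such as Gm6089 (1.66), the developmental factor En2 (1.01), Slc30a3 (-0.57), Wfs1 (-0.45) and Dpysl5 (0.28). Variants in that DNA were not analysed here. An effect of the allele on its neighbours stays open, untested.

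Other divisions of the animals tested chance. In 100 of the 200 divisions balanced by sex, 1, the real one, called as many genes as 1982, and the highest other called 807. Chance is therefore unlikely there, at 1 of 100. The divisions are not balanced by name prefix, so they cannot separate genotype from prefix. The highest other exchanges Q140 animal 5 and wild type 4, both of number 161 and in the neighbouring wells B09 and A09. That leaves a doubt about the values of wild type 4, which is taken up under the other observations. For males against females 1 of 100 reached 116, with 5 in the highest other. In females 1 of 10 reached 1249 and in males 1 of 10 reached 248, with 0 in the highest other in both, and 10 divisions are too few for a share below 0.05. For the difference between the sexes 100 of 100 had at least the real count of 0, as any count must, so this says nothing about chance. The highest other, 2096, exchanges the genotypes of the males, so that it measures the difference the sexes share and reflects a structure of the samples.

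Single animals lay apart from the others of their genotype in 28 of 414 groups of 6, or 6.76%, where chance gives about 1 in 20; each value is the gap to the nearest animal over the whole range. Wild type 4 did so for Htt (0.72), C130021I20Rik (0.707), Twist1 (0.785), Egr2 (0.633), Hspa8 (0.707), Kcnh3 (0.788) and the immediate early list mean (0.669). Wild type 6 did for Onecut2 (0.681), Gm6089 (0.857), Gm12031 (0.633), Mog (0.654), Bcas1 (0.653) and Ntng2 (0.63), and wild type 5 for H2-D1 (0.644), Ly6c1 (0.821), Hoxc4 (1) and the GABA receptor list mean (0.631). The value for Hoxc4 rests on the 1 read that all wild types held together, so it says nothing about wild type 5. Wild type 3 stood apart for Manf (0.635) and Pcdhga8 (0.77), and Q140 animal 2 for Dpysl5 (0.663). Q140 animal 3 did for Csf1 (0.686), Cd9 (0.627), Pcolce (0.655), Pcdhb14 (0.721) and the GABA receptor list mean (0.657), and Q140 animal 5 for Tnfrsf8 (0.737), Hbb-bs (0.675) and the red blood cell list mean (0.719).

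The Q140 effect on 15 lists differed between the sexes by camera with the preset correlation, and none by camera with an estimated one, where the adjusted p was 0.749 or more. Medians in females and males, with the camera adjusted p of the difference, were 0.34 and 0.02 for glucocorticoid-responsive genes (1.04e-05), 0.31 and 0.01 for endothelium (4.5e-05), 0.25 and 0.04 for endoplasmic reticulum stress (4.5e-05), 0.08 and 0.20 for ribosomal proteins (0.000104), 0.06 and -0.57 for striatal markers (0.000186) and 0.12 and -0.06 for astrocytes (0.000186). They were 0.40 and 0.19 for oligodendrocytes (0.000247), 0.53 and 0.10 for reactive astrocytes (0.000595), 0.33 and 0.09 for disease-associated microglia (0.00379), 0.13 and 0.02 for heat shock (0.00428), 0.92 and 0.15 for meninges (0.0111) and 0.38 and 0.10 for complement (0.0128). Cholesterol synthesis had -0.23 and -0.13 (0.0159), excitatory neurons -0.41 and -0.25 (0.0301) and mitochondrially encoded genes 0.18 and 0.05 (0.0301). The heat shock mean was 0.18 in Q140 animals 1 and 2, the females without a prefix, and 0.05 or lower in the other 10 animals, as the endoplasmic reticulum stress and glucocorticoid means were also highest in these 2 animals.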

How the results depend on the processing

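The settings with length and GC offsets, with the meningeal list mean and without wild types 3 and 6 were chosen only after the result was seen. Of 5120 values of 186 named results under the alternatives, 4414 kept their side of the threshold, and of these 3, none past it, took the other sign with the oligodendrocyte list mean; 590 kept the direction but no longer passed, 115 newly passed and 1 reversed: Lhx6, at 0.0209 among the animals of the numbers 150 and 161. Htt ranged from -0.40 to -0.28 over 29 alternatives and passed in 27. The genotype count of 1982 was 195 with the oligodendrocyte and 1062 with the meningeal list mean, 862 without wild types 3 and 6, 81 within the prefixes RFckQ and RFQ, 1 within the numbers 150 and 161, 684 and 3029 at adjusted p below 0.01 and 0.1, 365 at 1.5-fold, and 1139 to 2504 on leaving out each animal. In females, 1249 became 2716 by voom, 526 on unfiltered FPKM and 228 to 1426 on leaving out each animal; the 31 without wild types 3 and 6 leave 1 wild type female, assumed to vary like the other groups, and say nothing about stability. In males, 248 became 576 without a filter, 688 by DESeq2, 854 by voom, 472 on FPKM with either pseudocount, 63 in a fit of males alone, and 41 to 747 on leaving out each animal. The difference between the sexes gave 25 genes by DESeq2, 1 by voom, 5 on unfiltered FPKM and 0 to 4 on leaving out each animal. Males against females gave 220 without a filter, 350 by DESeq2, 47, 61 and 30 on FPKM, 35 without wild types 3 and 6, and 45 to 146 on leaving out each animal. The odds ratio near Htt was 1.35 at 20 Mb and 1.85 at 5 Mb. Of 39 lists, 0 passed with an estimated correlation, 14 by fry and 21 to 26 on leaving out each animal. Fits with fewer animals have fewer degrees of freedom; the cause of the other differences was not tested. No paired analysis was possible over all 12 animals because the labels give no replicate numbers and only the numbers 150 and 161 in the animal names join the genotypes; the fit within those 5 animals is given above.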

Other observations

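The tests of reads passing between neighbouring libraries were chosen only after the result was seen. Some genes of DNA repair and cell death changed. Of 13 mismatch repair genes and related nucleases, a class that acts on expanded repeats, 2 rose, 0 fell and 11 did not pass, and 2 were higher adjusted over the list alone: Mlh3 (0.18, adjusted p = 0.00936) and Pcna (0.18, adjusted p = 0.0433, past in 11 of 29 alternatives), with a camera adjusted p of 0.386 and a fry adjusted p of 3.05e-06 for change in either direction. Among 16 apoptosis and p53 targets Eda2r, a death receptor gene, rose by 1.65 (SE 0.193, adjusted p = 0.000207) and the kinase gene Plk2 fell by 0.38 (SE 0.0452, adjusted p = 0.000251), 14 did not pass, and 2 were higher and 2 lower adjusted over the list alone, with Gadd45a (0.34) and Cdkn1a (-0.37) the others. Camera gave an adjusted p of 0.967, and fry 3.27e-08 for change in either direction. That form of fry does not compare a list with other genes, and 27 of 39 lists passed it. With 11.2% of all tested genes called, these values do not set the repair or the p53 list apart. Of 12 proliferation genes 0 passed, over all genes or adjusted over the list alone (median -0.14, camera adjusted p = 0.328).

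Clustered protocadherins, cell surface genes that share exons, gave 3 higher and 2 lower of 56, and 2 of each adjusted over the list alone (camera adjusted p = 0.595), with Pcdhgc5 at -0.43 and Pcdhb14 at 0.39. Their shared exons make single members uncertain. Of 15 piriform layer markers 2 rose and 3 fell, the same numbers adjusted over the list alone: Etv1 at 0.40 and Tle4 at 0.26 against Cux2 at -0.31 and Lhx2 at -0.23, past in 15 of 29 alternatives (camera adjusted p = 0.456). Among 13 immature neuron markers Dpysl5, of growth cones, rose by 0.28 (adjusted p = 0.0247), with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.839). Of 16 markers of other neighbouring regions Prox1 rose by 0.37, Wfs1 fell by 0.45 and Ntng2 by 0.64, but Ntng2 passed in 9 of 29 alternatives (-0.74 to -0.27), was at -0.39 without wild type 6 and overlaps 6530402F18Rik on its strand, with 2 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.907).

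Lower clock genes could reflect an earlier or later hour of dissection in the Q140 animals. That would raise Arntl, which cycles in antiphase to Per1 and its partners. Arntl was at -0.15 (95% interval -0.29 to -0.02, edgeR adjusted p = 0.125), below the bound set for the test. This goes against the prediction but rests on Arntl alone. Neuronal genes fell in the same animals, and a general fall could hide a rise of Arntl, so the test cannot decide.

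Wild type 4 lay nearer to the Q140 animals than other wild types did, and reads of Q140 animal 5, from the neighbouring well, could be a cause. Over 77 genes changed at least 2-fold in a fit without either animal, wild type 4 lay a median share of 0.405 of the way from the other wild types to Q140 animal 5 (95% interval 0.133 to 0.537), against 0.544 for Htt (0.296 to 0.791), which leaves mixing open. The same median was 0.211 to 0.405 for wild type 4 with each Q140 male, and -0.0605 to 0.216 for the other wild types with Q140 animals of their sex. Mixing gives every gene the same share, and over 12 genes that rose at least 4-fold, in a test added after the earlier one, the pooled share was 0.0939 (0.0430 to 0.261), or 0.146 (0.0380 to 0.318) without Onecut2, which gives most of the reads, while Twist1 alone had 0.734. The interval over the 12 genes lies below the lower limit for Htt, 0.296, while the one without Onecut2 spans it. Hoxc4, Hoxc6 and Gm2420, all of low level, had 0 CPM in wild type 4, against 0.546, 0.890 and 0.373 CPM in Q140 animal 5. The interval over the 77 genes also spans that limit, so mixing and a likeness of the animals themselves cannot be told apart.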
